A study of Homo sapiens with 19 samples.

How the data were processed

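The series holds 19 Affymetrix expression arrays of 10 human colon cancer cell lines, 5 MSI and 5 MSS as the labels give them. Total RNA was purified on columns and labelled with biotin by a one-cycle protocol, per the labels' protocols. The deposited values are on the log2 scale, and the submitters' processing notes name RMA, which corrects background, normalizes between arrays and summarizes probes per probe set. Its version and settings are not given in the sources used here. The log2 scale was read from the values, which run from 2.78 to 14.92. Both deposited tables hold the same values, with a largest difference of 0. The authors' deposited table also has a key for columns of means and a t-test, and values of such columns are not analysed here. No normalization was added, no count or depth exists for arrays, and the number of lines limits the precision.

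The table has 54675 probe sets. The 62 control probe sets were left out of the tests, which leaves 54613. In the given platform annotation 41091 of these name 1 gene, 1801 name several and 11721 are unnamed here. Of the single-gene probe sets, 41037 matched a gene table of assembly GRCh38.p14 through the Entrez number, and no symbol had to be updated. That table was used for names, chromosomes and the order of genes. No reference genome was used. Each of 19775 genes was represented by the single-gene probe set with the highest mean over the 10 line values, with no filter on dim probe sets. The deposited values have a median of 5.67 log2, and low values near the array background understate differences.

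The cell line is the replicate, following the series design: arrays of a line were averaged and 5 MSI lines were compared with 5 MSS lines. T84 has 1 array. The culture numbers of the labels were not used in the main tests to pair arrays of different lines. The E2 minus E1 differences of the 9 lines with duplicates correlated across probe sets at r from -0.21 to 0.27. The median r was 0.03, with 7 of 36 pairs over 0.1, so a shift shared by some lines is not excluded. Genes and probe sets were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The same fit on the 19 arrays with a moderated F test gave the genes that differ between lines, for which p-values measure only the spread between duplicate cultures. The shares of the sum of squares were taken per gene, without division by degrees of freedom and without a test.

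Gene lists, 27 in all, were tested with limma camera at a preset correlation of 0.01, with a minimum of 5 measured members. Camera compares a list with all other genes, so its direction is relative to them. Camera with an estimated correlation and fry, which tests whether a list moves on balance one way and makes no comparison with other genes, were run as alternatives. A list score is the mean over members of the log2 value minus the mean of that gene over the 10 lines. Intervals of the RNA quality measures hold the shifts that an exact permutation test did not reject. Chromosomes 1 to 22 and X were tested with camera in the same way.

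The genes named were chosen by a rule. In each direction it takes the 12 largest differences among genes past the threshold. Where fewer than 12 pass, it adds, up to 12, genes in which all lines of 1 status lie above all of the other and the difference is at least 1 log2, in order of unadjusted p. It takes the members of each described list that passed, or otherwise the 3 with the smallest p, and genes tied to the MSI label, of which EPM2AIP1 and MSH6 are given. The other genes of that last part are not reported here. XIST and Y-linked genes are not named.

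The fits were tested on simulated data for the same 19775 genes with 50 genes changed at each of 4 sizes. In the simulated MSI against MSS comparison, 38% of genes changed by 1 log2 were recovered, 82% at 2 log2, 96% at 4 log2 and 94% at 6 log2, with 11 false among 166 calls. Of 200 simulated lists drawn at random, 2% had a camera p under 0.05. Some of their members could be among the changed genes, so these lists were not strictly without a change. The simulated genes varied independently of each other. Members of the real lists vary together, with an estimated correlation of up to 0.68 for the hepatocyte-like markers. The simulation therefore cannot show how often camera calls such lists without a change.

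The comparisons with their main tests, the gene lists, the rule for named genes and all alternatives except 1 were fixed before the data were examined. Some tests of explanations were chosen only after the results were seen. They are those of the whole transcript level, of RNA integrity, of single lines and of chromosomes over other splits. The alternatives were median centring, a second quantile normalization, filters on dim and on invariant genes, other ways to represent a gene, trend and robust eBayes, equal-variance and Welch tests, array weights, fits on all arrays with the line as a random block, single cultures, and leaving out each line in turn. An exact permutation test of list scores was added after the data were seen. For chance, 100 of the 126 ways to split the 10 lines into groups of 5 were drawn, the real one included, and refitted. Lines that stand apart were found with Dixon's ratio at the critical value of 0.71 for 5 values. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.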

Results

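Expression was measured on Affymetrix arrays in 10 established colorectal cancer cell lines, grown untreated and harvested in exponential growth. The labels place 5 lines in the microsatellite unstable group (MSI: RKO, SW48, HCT116, LIM2405 and LS174T) and 5 in the microsatellite stable group (MSS: HT29, T84, CACO2, SKCO1 and HCC2998). Microsatellite instability is the accumulation of length changes in short DNA repeats that follows loss of mismatch repair. Of the 19 arrays, 10 came from MSI lines and 9 from MSS lines. Duplicate cultures were arrayed for 9 lines and 1 culture for T84. The cell line was the replicate throughout, so each line entered as the mean of its arrays and n = 5 per group. All differences are MSI minus MSS on the log2 scale, errors of group means are SDs between lines, and the number of lines limits the precision.

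The first question was how far lines of the same status differ from each other. Of 19775 genes, 13247 (67.0%) differed between the 10 lines against the spread between duplicate cultures. Within the MSI group 11707 genes differed between lines, and within the MSS group 8789 did. Each group was fitted against its own duplicates alone, and T84 has none, so these counts do not rank the groups by heterogeneity. All 30 measured genes of epithelial junctions and keratins and all 30 interferon-stimulated genes were among those that differed, against 1 of 10 endothelial markers. The hepatocyte-like markers, a list of secreted liver proteins such as APOH, SERPINA1 and FGB, had a score (mean log2 difference from the mean over lines) of 5.01 in CACO2 and of -0.86 to 0.13 in the other MSS lines. Over all genes, the median share of the sum of squares was 7.9% between MSI and MSS. It was 71.2% between lines of the same status and 13.0% between duplicates. These shares were not divided by degrees of freedom, of which status has fewer than lines or duplicates. They therefore do not weigh status against line. The median SD was 0.401 between lines of the same status and 0.187 between duplicates. Duplicate cultures correlated across probe sets at Pearson's r from 0.9777 in HT29 to 0.9961 in HCT116 and LIM2405. These correlations are across probe sets, which are not independent replicates.

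The comparison of MSI with MSS lines, the contrast of the series, gave 9 changed genes of 19775, of which 5 were higher and 4 lower in MSI lines. OXCT1, a mitochondrial enzyme of ketone body use, was 18.4-fold higher in MSI lines (9.31 ± 0.71 against 5.11 ± 0.54 log2, n = 5 each, adjusted p = 0.00886). The metallothionein genes MT1G and MT1F, whose products bind zinc and copper, were 10.5-fold and 9.93-fold higher. ARHGAP44 was higher by 3.03 ± 0.38 log2 (SE, adjusted p = 0.0417), and NEIL2, a DNA glycosylase of base excision repair, by 1.26 ± 0.16 (SE, adjusted p = 0.0413). PLTP, the phospholipid transfer protein, was 10.4-fold lower in MSI lines, at 5.56 ± 0.37 against 8.94 ± 0.81 log2 (adjusted p = 0.0193). SEC22B, a vesicle fusion protein of the endoplasmic reticulum and Golgi, was 6.64-fold lower. RNLS, which encodes renalase, fell by 2.66 log2 (SE 0.22, adjusted p = 0.00872), and PPP1CB, a catalytic subunit of a protein phosphatase, was 5.71-fold lower. In each of the 9 genes, all 5 lines of 1 status lay above all 5 lines of the other. The number of changed genes was 54 without LS174T, 14 without CACO2 or without T84, 5 without HCT116, 4 without RKO, 3 without SKCO1 and 2 without SW48. OXCT1 and RNLS passed the threshold whichever single line was left out.

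**Figure D1:**
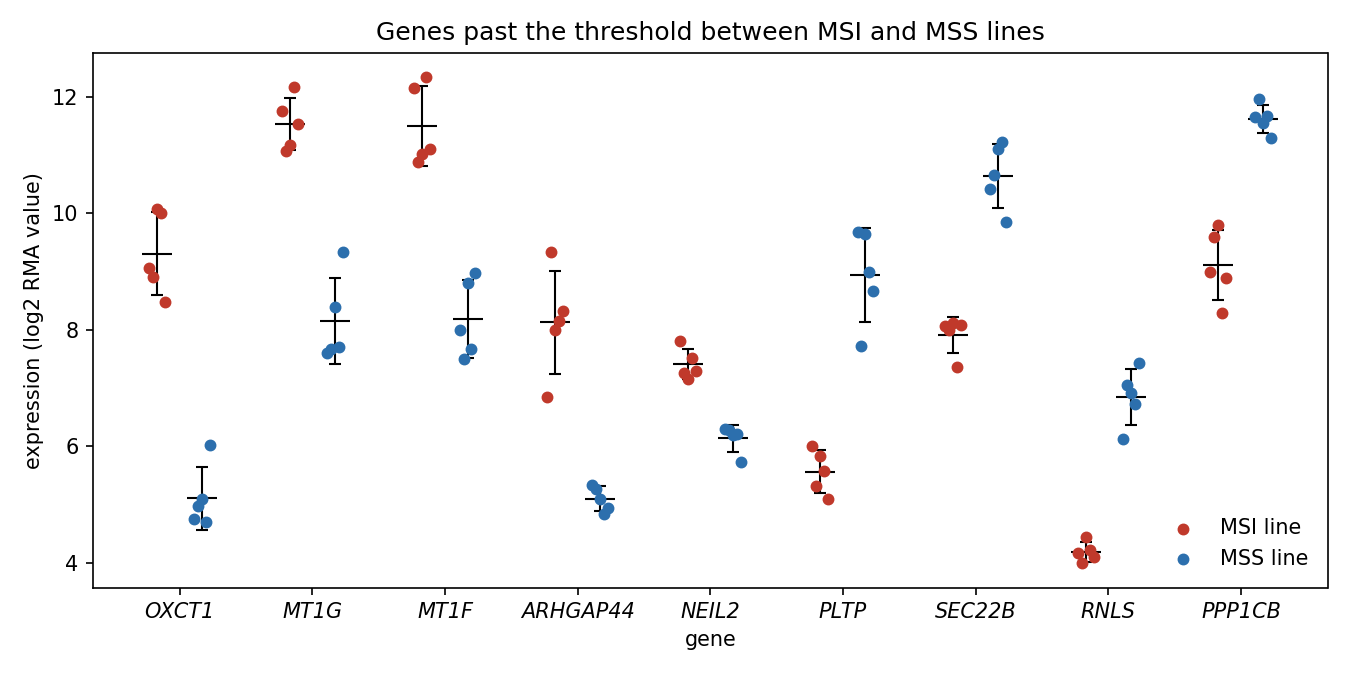
Log2 RMA value (vertical axis) of the 9 genes past the threshold (horizontal axis) in each cell line. Each point is the mean of the arrays of a line, horizontal bars are group means over 5 lines and error bars are SDs. OXCT1 lay at 8.48 or above in MSI lines and at 6.02 or below in MSS lines, and the MSI and MSS points do not overlap for any gene shown.

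The other 3 probe sets of PPP1CB, at means of 9.28 to 10.13 log2, differed by 0.08 to 0.38, against -2.51 for the brightest one that represents the gene. The other probe sets of RNLS and SEC22B differed by 0.06 and -0.82, at means of 4.46 and 4.85 log2, under the median of 5.67 of all values, where a fall is hard to see. As the mean of all its probe sets, PPP1CB differed by -0.48 (adjusted p = 0.528) and SEC22B by -1.78 (adjusted p = 0.178). The other probe set of ARHGAP44, at a mean of 6.03 log2, differed by 0.53, and as the mean of both the gene differed by 1.78 and still passed the threshold. The brighter MT1G probe set has the suffix of probes that can match near-identical genes, as do both MT1F probe sets. The other MT1G probe set, without that suffix, lay at 4.54 log2 on average and differed by 0.22.

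Genes that separated the groups completely without passing the threshold over genes are given here by their values. In the limma test over all probe sets, the probe sets that represent KALRN, RUFY2, C4BPB and FAM76A did not pass (adjusted p = 0.0550 to 0.0609). Those of the other genes named in this paragraph did (adjusted p = 0.0344 to 0.0436). SMAD9, a transcription factor of BMP signalling, lay at 8.68 ± 1.32 log2 in MSI and 4.42 ± 0.47 in MSS lines (n = 5 each, adjusted p = 0.0583). KLHL29 lay at 8.93 ± 1.09 and 4.93 ± 0.73, and ZNF618 and the splicing factor HNRNPL differed by 3.32 and 2.01, each with an adjusted p = 0.0583. The other probe sets of SMAD9 and KLHL29 differed by 0.39 and by 0.25 to 1, and as means of all their probe sets these genes differed by 2.32 and 1.42. The metallothioneins MT1X and MT1H differed by 3.93 and 3.57. RPL22L1, a paralog of the ribosomal protein gene RPL22, lay at 12.61 ± 0.35 in MSI and 10.70 ± 0.57 in MSS lines (adjusted p = 0.0701). On the other side, ALDH1A1, a retinaldehyde dehydrogenase, lay at 4.90 ± 1.43 in MSI and 11.18 ± 1.48 in MSS lines, 77.7-fold lower in MSI (adjusted p = 0.0583). That fold is rough, since the MSI mean lies under the median of 5.67 of all values and includes LS174T at 7.44. Over the alternatives the difference ran from -6.91 to -5.91. PURA, XYLT2 and LOC105372255 differed by -2.98, -1.28 and -1.03 at the same adjusted p. The other probe sets of PURA differed by -0.67 to -0.01 and those of XYLT2 by -0.12 and 0.06, and as means of all their probe sets these genes differed by -0.78 and -0.45. KALRN, RUFY2, the complement regulator C4BPB and FAM76A differed by -2.51, -2.16, -2.90 and -2.24 (adjusted p = 0.0886 to 0.0944). The other 6 probe sets of KALRN differed by -0.54 to 0.13, and as the mean of all it differed by -0.46. The brightest other probe set of RUFY2 differed by -2.55, and 3 dimmer ones lay in the opposite direction by 0.61 to 0.75. Both other probe sets of FAM76A differed by 0.18 and 0.25. Over all genes, 512 (2.59%) separated the groups completely, 394 higher and 118 lower in MSI lines. By chance 0.794% would on average. How far this share varies over other splits was not computed, so the excess was not tested. At an unadjusted p under 0.05 there were 1932 genes, 1337 higher and 595 lower.

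Taken probe set by probe set, 103 of 54613 changed, 26 higher and 77 lower in MSI lines. Of these, 68 named 1 gene, for 59 distinct genes in all. The genes named next were chosen after their values were seen. The higher probe sets included SRSF6, a splicing factor, with a difference of 3.63 (SE 0.41, adjusted p = 0.0139) and ATXN7 with 1.49 (adjusted p = 0.011). The lower ones included IGF1R, the receptor of insulin-like growth factors, with -4.20 (adjusted p = 0.00786), RBM6 with -4.32, TOB1 with -4.21 and SET with -2.76 (adjusted p = 0.00274). Among the lower probe sets, 43 belonged to 36 genes that have another probe set. Their median difference was -2.51, and that of the brightest other probe set of the same gene was -0.40. Of the 36 distinct other probe sets, 7 lay lower by at least 1 log2, as for CGN (-2.65) and USH1C (-2.83), 8 were lower at an unadjusted p under 0.05 in limma and 0 passed the threshold. The brightest other probe set of SET differed by 0.78, that of TOB1 by -0.05 and that of RBM6 by 0.08. That of SET has the suffix of probes that can match near-identical genes, so its value may not be that of SET alone. The number of changed probe sets was 261 without CACO2, 66 without HT29, 56 without SKCO1, 48 without HCT116, 47 without HCC2998, 33 without SW48 and 29 without RKO.

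**Figure D2:**
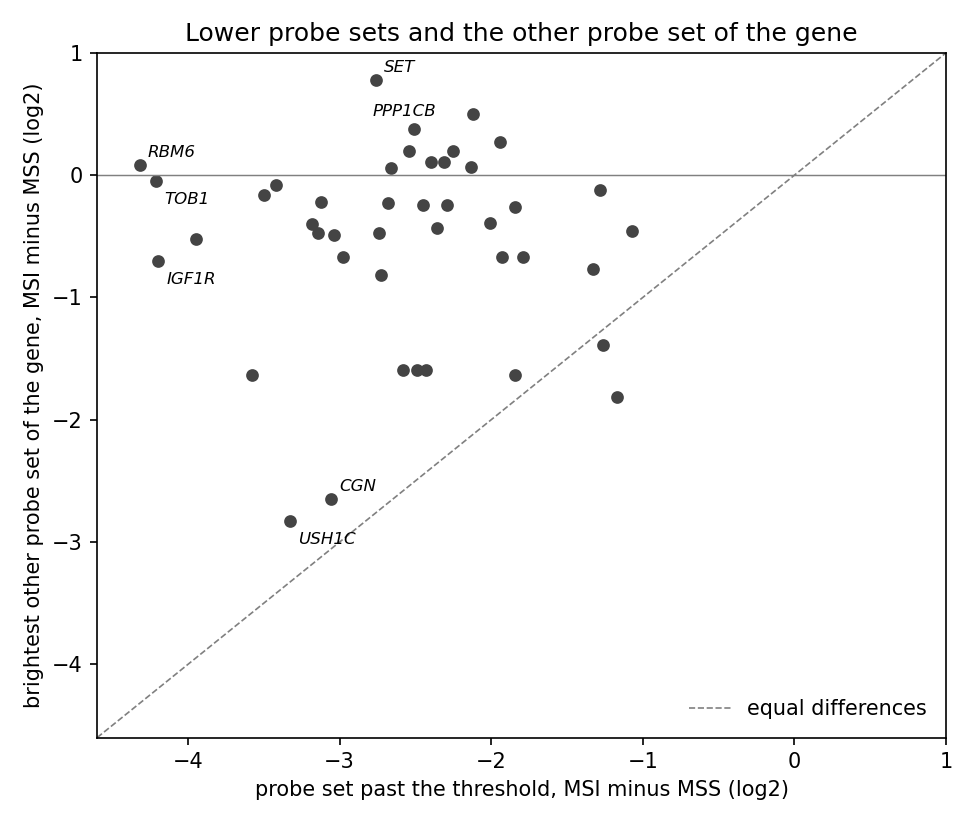
MSI minus MSS difference in log2 of 43 probe sets lower in MSI lines (horizontal axis) against the difference of the brightest other probe set of the same gene (vertical axis). Each point is 1 such probe set and the dashed line marks equal differences. The median is -2.51 on the horizontal and -0.40 on the vertical axis, and genes with several lower probe sets, such as ADD3, share 1 value on the vertical axis.

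Gene lists asked which functions differed. Of 27 lists, 15 passed the threshold with a preset correlation between genes of 0.01, 13 lower and 2 higher in MSI lines. With an estimated correlation only the list of genes with coding repeats held. Of 608 distinct list genes, 0 passed the limma threshold over all genes and 102 had an unadjusted p under 0.05, so members are given by their values and by counts adjusted over the list alone.

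Genes of epithelial junctions and keratins were lower in MSI lines in 29 of 30 cases (adjusted p = 9.52e-14; adjusted p = 0.178 with an estimated correlation). CLDN1 and CLDN2, which encode claudins of tight junctions, passed when adjusted over the list alone, at 6.34 ± 1.81 against 10.94 ± 0.65 and 5.70 ± 0.45 against 9.01 ± 1.55 log2 (n = 5 each). TJP3 differed by -1.35. In RKO the mean score of this list was -3.25, and in the other MSI lines it was -0.15 to 0.15. Serine proteases, mucins and carcinoembryonic antigens were lower for 20 of 22 genes (adjusted p = 1.30e-09; adjusted p = 0.178 with an estimated correlation). CEACAM1 and TMPRSS2 passed when adjusted over the list alone, with differences of -4.26 and -2.55, and MUC20 differed by -3.41. Among the MSS lines CACO2 had a score of -1.38, below the -0.52 of SW48, and among the MSI lines LS174T had a score of 1.25, against -2.55 to -0.52 in the others.

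Enterocyte and brush border genes were lower in MSI lines for 27 of 33 members (adjusted p = 1.12e-08; adjusted p = 0.178 with an estimated correlation). The intestinal keratin gene KRT20 lay at 5.64 ± 0.57 in MSI and 11.41 ± 3.27 in MSS lines, and USH1C, which encodes a scaffold of microvilli, at 7.21 ± 1.67 and 10.04 ± 0.25. Both passed when adjusted over the list alone, and TM4SF5 differed by -1.48. LS174T stood apart from the other MSI lines, with a score of 0.73 against -0.86 to -0.66. Intestinal transcription factors were lower for 17 of 19 genes (adjusted p = 2.15e-06; adjusted p = 0.152 with an estimated correlation), with FOXA3 at -2.23, ISX at -2.93 and HOXB13 in the other direction at 0.74. Wnt targets and stem cell genes were lower for 21 of 28 genes (adjusted p = 4.35e-05; adjusted p = 0.178 with an estimated correlation). SP5 and ASCL2 differed by -1.71 and -3.12, while MYC differed by 1.04. None of these transcription factor or Wnt genes passed when adjusted over the list alone.

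Xenobiotic metabolism and transport genes were lower for 22 of 28 members (adjusted p = 1.43e-07; adjusted p = 0.152 with an estimated correlation). When adjusted over the list alone, 5 were lower and 1 was higher. The lower ones were ALDH1A1, the glucuronosyltransferase gene UGT1A6 (-2.22), the cytochrome gene CYP3A5 (-3.25), the transporter gene ABCC3 (-2.56) and the reductase gene AKR1C2 (-2.82), and the higher one was the glutathione transferase gene GSTM1 (0.77). In LS174T the score of this list was 0.56, against -1.18 to -0.73 in the other MSI lines.

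Further lists passed with the preset correlation without any member passing when adjusted over the list alone. Interferon-stimulated genes were lower for 26 of 30 genes (adjusted p = 1.47e-06; adjusted p = 0.391 with an estimated correlation), with EPSTI1 at -2.86, MX2 at -1.87 and OAS1 at -3.33, and T84 had a score of 2.82 against -1.10 to 0.70 in the other MSS lines. Goblet and secretory cell genes were lower for 15 of 22 genes (adjusted p = 9.89e-04; adjusted p = 0.409 with an estimated correlation). AGR2, SPINK1 and MUC13 of that list differed by -6.48, -4.94 and -3.14, and LS174T had a score of 1.94 against -1.19 to -1.13 in the other MSI lines. Mesenchymal genes were higher for 23 of 29 genes (adjusted p = 0.0227; adjusted p = 0.256 with an estimated correlation), with TGFB1I1 at 2.10, LGALS1 at 3.50 and ZEB2 at 0.22. Without HCT116 the adjusted p of this list was 0.226, and without T84 it was 0.0759.

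The calls of 4 more lists depended on which lines were included. Hepatocyte-like markers were lower for 11 of 14 genes (adjusted p = 0.00366; adjusted p = 0.563 with an estimated correlation). APOH, SERPINA1 and FGB differed by -2.74, -1.92 and -1.09, and without CACO2 the direction turned, with an adjusted p of 0.831. Gastric-type markers were lower for 12 of 15 genes (adjusted p = 0.00762; adjusted p = 0.230 with an estimated correlation, and 0.0703 without SKCO1), with PGC at -0.39, ANXA10 at -1.78 and MUC5AC at -0.76. TGF-beta and BMP response genes were lower for 16 of 25 genes (adjusted p = 0.0295; adjusted p = 0.409 with an estimated correlation). The adjusted p was 0.521 without SKCO1, 0.147 without RKO and 0.0724 without LS174T. TGFBR2, TGFBI and SMURF2 of that list differed by -2.41, -4.17 and 2.06. Cell cycle and proliferation genes were lower for 21 of 34 genes, with a median difference of -0.07 (adjusted p = 0.0398; adjusted p = 0.709 with an estimated correlation), with UBE2C at -0.62, CCNE1 at 0.88 and TOP2A at -0.55. The adjusted p of the cell cycle list was 0.678 without CACO2, 0.380 without LS174T, 0.348 without SKCO1, 0.202 without LIM2405 and 0.197 without RKO. No member of these 4 lists passed when adjusted over the list alone.

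Genes with coding repeats that are known to be mutated in MSI cancers were lower in MSI lines for 23 of 29 members, with a median difference of -0.30 and a mean of -0.58. The call (adjusted p = 1.93e-06) held with an estimated correlation (adjusted p = 0.012) and with fry (adjusted p = 0.0102). MARCKS, a substrate of protein kinase C, lay at 9.07 ± 0.96 in MSI and 11.47 ± 0.64 in MSS lines (n = 5 each) and passed when adjusted over the list alone. TGFBR2, a receptor of TGF-beta, lay at 8.85 ± 1.47 and 11.27 ± 0.41, with all 5 MSI lines below all 5 MSS lines, and CASP8 differed by -0.74. Members were uneven, as examples chosen after their values were seen show. RNF43 and GRB14 differed by -2.30 and -2.22, but ACVR2A, ASTE1, RAD50 and TAF1B by -0.02, -0.13, 0.15 and 0.18. The mean score of the list was below 0 in every MSI line, from -0.61 to -0.10, and above 0 in every MSS line, from 0.14 to 0.35. In an exact two-sided permutation test of this score p = 0.00794, the smallest value that 5 lines against 5 can give, and adjusted over the 27 lists it was 0.0714.

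A list of p53 target genes, labelled selected damage-inducible genes in the figure, was higher in MSI lines for 23 of 29 members. Its camera adjusted p was 5.74e-04, and 0.178 with an estimated correlation. The list does not stand for the DNA damage response as a whole. CDKN1A, an inhibitor of cyclin-dependent kinases, lay at 10.75 ± 0.38 in MSI and 8.90 ± 0.84 in MSS lines and passed when adjusted over the list alone. ZMAT3 and SPATA18 differed by 1.54 and 0.46, although ZMAT3 differed by -0.36 (adjusted p = 0.9002) when the probe set with the largest interquartile range represented it. The directional fry test of this list gave an adjusted p = 0.0245. The separate list of homologous recombination and DNA damage repair did not pass (adjusted p = 0.127).

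**Figure D3:**
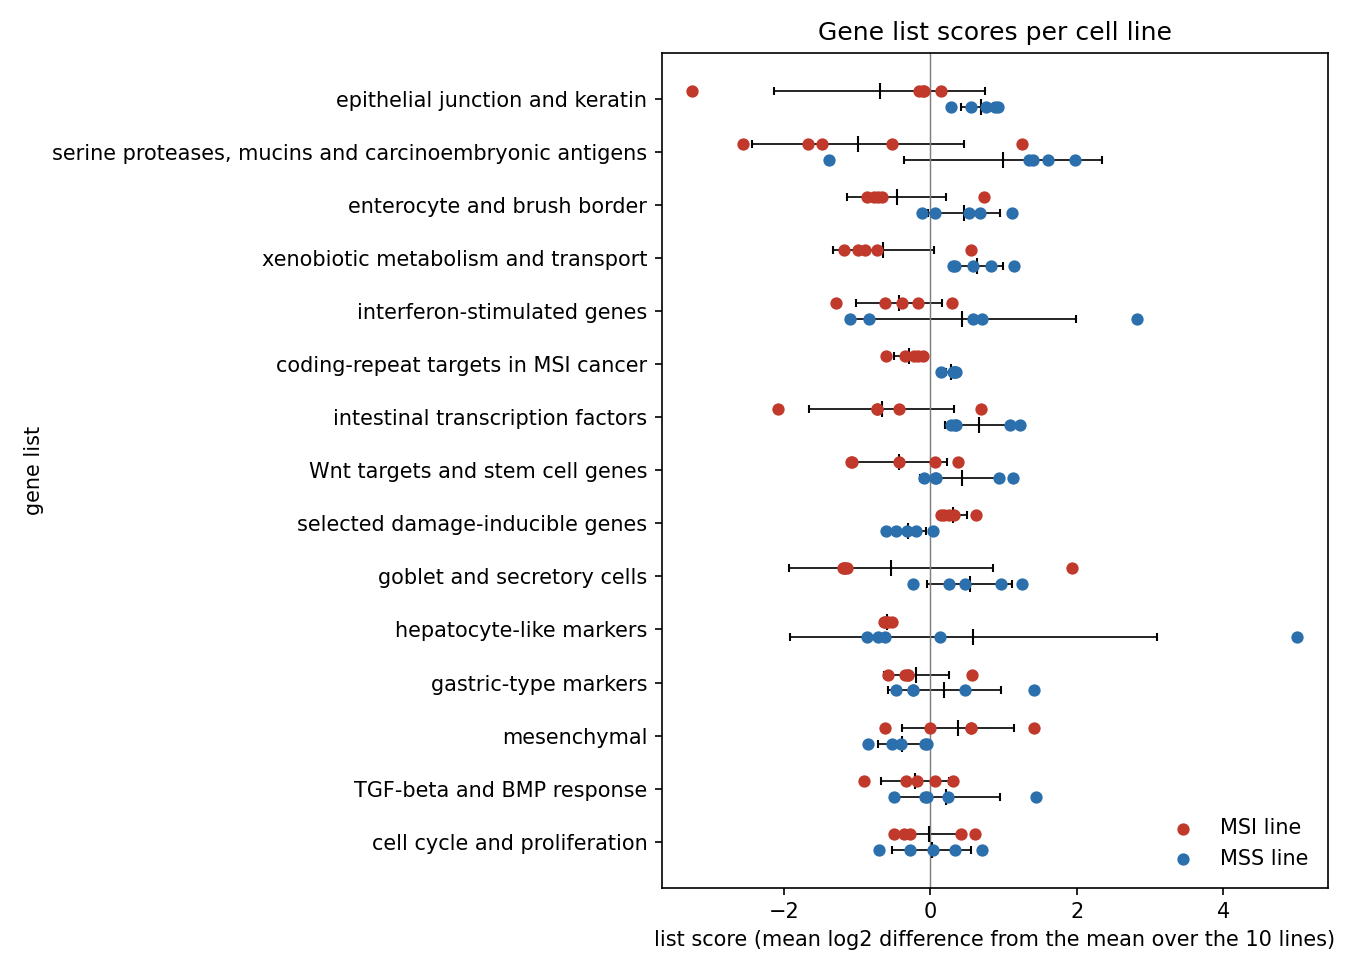
Mean score (horizontal axis, mean log2 difference of the members from their mean over the 10 lines) of the 15 lists past the threshold with a preset correlation (vertical axis). Each point is a cell line, ticks are group means over 5 lines and error bars are SDs. The coding-repeat list separates the groups, at -0.61 to -0.10 in MSI and 0.14 to 0.35 in MSS lines. So do the junction list and the p53 target list, which is labelled selected damage-inducible genes. The hepatocyte-like score of 5.01 belongs to CACO2 alone.

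The other 12 lists did not pass. Mismatch repair genes were higher for 10 and lower for 10 of 20 measured members (camera adjusted p = 0.140). RFC5 differed by -0.90 and PMS1 by 0.52. Of the 23 listed genes 20 were measured, EPM2AIP1 among them, so the list cannot show that mismatch repair as a whole was unchanged. EPM2AIP1, fixed in advance as a gene tied to the MSI label, lay at 3.55 in LIM2405, 4.16 in SW48 and 4.22 in RKO, at 10.09 in HCT116 and 9.18 in LS174T, and at 8.59 to 11.22 in the MSS lines, a mean difference of -3.85 (SE 1.36, adjusted p = 0.393). MSH6, a subunit of the mismatch recognition complex, differed by -0.26 (95% interval -1.09 to 0.57). In homologous recombination and DNA damage repair (adjusted p = 0.127), MRE11, a nuclease of double-strand breaks, lay at 7.79 ± 0.37 in MSI and 9.05 ± 0.31 in MSS lines and passed when adjusted over the list alone. Hypoxia and glycolysis genes had an adjusted p = 0.0713, cholesterol and fatty acid synthesis 0.0994, EGFR ligands and MAPK output 0.400, HOX genes 0.644, the CpG island methylator panel 0.944 and antigen presentation 0.989. In the enteroendocrine and neural-like list (adjusted p = 0.860), ENO2, a neuronal enolase, passed when adjusted over the list alone with a difference of 2.76. Markers of other cell types gave an adjusted p = 0.430 for immune cells, 0.631 for fibroblasts and 0.660 for endothelium. The immune list had a mean difference of -0.42 and a median of 0.01.

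Lines of the MSS class often carry gains and losses of whole chromosomes, so genes were also grouped by chromosome. None of the 23 chromosomes passed with limma camera (lowest adjusted p = 0.0589, for chromosomes 11, X and 8), and with an estimated correlation the lowest adjusted p was 0.898. At an unadjusted p under 0.05 there were 8 chromosomes, and 0 with an estimated correlation. Genes of chromosome 8, which holds NEIL2, had a median difference of 0.125, against 0.071 for all genes, and those of chromosomes 11 and X medians of 0.012 and 0.013, above 0 although lower relative to the other genes. With a filter on dim probe sets 6 chromosomes passed. Without SKCO1 5 passed, without HCC2998 4, without CACO2 or SW48 2 each, and without T84 1.

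Control probe sets at both ends of the GAPDH and beta-actin transcripts gave a measure of RNA quality. The 3-prime minus 5-prime difference for GAPDH was 0.29 ± 0.21 in MSI and 0.30 ± 0.25 in MSS lines (n = 5 each, exact two-sided permutation p = 0.984, 95% interval of the difference -0.36 to 0.33). For beta-actin it was 1.24 ± 0.70 and 1.09 ± 0.52 (exact permutation p = 0.698, 95% interval -0.67 to 1.12). LS174T had the highest actin value, 2.31, followed by T84 with 1.90.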

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

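The tests of the whole transcript level, of RNA integrity and of single lines were chosen only after the results they concern were seen. Dixon's ratio marked 15 of 112 groups of 5 lines, where chance marks about 1 in 20 groups. A line far from the other 4 of its status was found for several named genes. LS174T lay above the other MSI lines for ALDH1A1 (7.44 log2, next highest 4.41), KALRN (7.76, next 6.64) and C4BPB (7.67, next 6.40). RKO lay below the other MSI lines for SEC22B (7.37, mean of the others 8.06), and T84 below the other MSS lines for NEIL2 (5.73, next 6.20).

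Among list scores, LS174T was high among the MSI lines for goblet and secretory genes (1.94, next -1.13), enterocyte genes (0.73, next -0.66), gastric-type markers (0.57, next -0.30) and xenobiotic metabolism (0.56, next -0.73). RKO was low for epithelial junctions and keratins (-3.25, next -0.15), and LIM2405 for fibroblast markers (-0.18, next 0.07). Among the MSS lines CACO2 was high for hepatocyte-like markers (5.01, next 0.13), low for EGFR ligands and MAPK output (-1.23, next -0.20) and low for serine proteases, mucins and carcinoembryonic antigens (-1.38, next 1.35). HT29 had the lowest MSS score of the coding-repeat list (0.14, next 0.31), which still lay above every MSI line.

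A pattern to follow up is the set of 43 probe sets lower in MSI lines, of genes such as IGF1R, TOB1, RBM6 and SET. A lower level of the whole transcript would lower the other probe sets too, but over the 43 the brightest other one had a median difference of -0.40 (quartiles -0.74 and 0.00) against -2.51; a first version, which left out other probe sets that were themselves lower, was replaced after its result was seen. The lower probe sets were chosen for passing the threshold and the others were not, so a smaller difference in the others is partly built in. Only the brightest other one was used, and TRAK1, CSNK1A1, SASH1, AKAP1 and CDC14B each had several lower probe sets past the threshold. A lower whole transcript therefore was not excluded for any single gene. It stays open most plainly for the 7 genes whose other probe set was also lower by at least 1 log2, CGN, USH1C and ADD3 among them. RNA integrity, as actin measures it, was examined with 43 probe sets chosen as lower on 6 lines alone, 15 of them among the lower ones above. In those 6 lines actin 3-prime minus 5-prime was higher in MSI (1.65 against 0.80). In the lines left aside, SW48 and HCT116 against SKCO1 and T84, it was lower in MSI (0.63 against 1.53). There the chosen probe sets still lay at a median of -1.28 (quartiles -2.22 and -0.65). The choice did not ask whether the other probe sets of these genes were unchanged. A gene lower over its whole transcript would stay lower whatever the integrity, so the test cannot decide for this pattern. Earlier tests with a GAPDH covariate and with these lines on the probe sets of the pattern itself decided nothing either. Integrity as a cause therefore stays open. Open, as an untested hypothesis tied to MSI status, is that length changes in A-rich or untranslated repeats may alter 3-prime ends or priming at the probed sites, which would need probe and genome sequences not used here.

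The metallothioneins are the next pattern. Over 8 genes, MT1E and MT2A included, the mean difference was 3.45, and it stayed at 3.16 or above whichever line was left out, so no single line carried it. Signal shared between near-identical paralogs remains open: between 10 probe sets of different genes the line profiles, after removing the status means, correlated at a median r of 0.84 (range 0.19 to 0.98), short of the 0.9 set in advance for a shared signal and above the 0.5 set against it. All 10 have the suffix of shared probes, and the MT1G probe set without it differed by 0.22 and the MT1M one by 2.02. A rise of all these genes and a rise of a few abundant ones therefore cannot be told apart, and a biological difference tied to MSI status was not tested.

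The coding-repeat genes lower in MSI lines were weighed against expression level and single lines. The list median of -0.30 stood at percentile 0 of 10000 random lists matched on mean expression, whose central 95% ran from -0.09 to 0.22, so brightness did not account for it. Leaving out any 1 line kept the mean difference at -0.50 or lower, the value nearest 0 being that without RKO. A biological explanation tied to MSI status, frameshifts followed by decay of the altered transcripts, may apply but stays a hypothesis, since no sequence was analysed here.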

How the results depend on the processing

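The exact permutation test of list scores was chosen after seeing the data; all other settings were planned. Under the settings that give a direction, named genes and called lists kept theirs with 2 exceptions: ZMAT3 (difference -0.36) with the probe set of largest interquartile range, and hepatocyte-like markers without CACO2 (adjusted p 0.831; the lowest without 1 line was 5.39e-04, without SKCO1). Of the other values of named genes under alternatives, 1551 kept their side of the threshold, 156 moved past it and 63 lost it; of those of called lists, 186 kept it and 53 lost it. Against 9 changed genes there were 16 with centred medians, 21 and 30 with filters on dim and on invariant genes (fewer genes tested), 62 with the probe set of largest interquartile range, 16 with trend and robust eBayes, 17 with array weights, 14 with cultures E2 alone and 4 with cultures E1 alone. An equal-variance t-test gave 1 gene (RNLS), a Welch test 0 (1766 at an unadjusted p under 0.05), and all 19 arrays with the line as a random block 350. Adding the culture number, which was not shown to pair the lines, as a fixed replicate block gave 304 genes. It gave 1006 probe sets, against 103 on line means, and 15 lists. Both fits on all 19 arrays let duplicate cultures add to the number of observations, so their counts do not rest on 5 lines per group. All 9 genes were among those called with centred medians, the dim filter, array weights and both block fits. The equal-variance t-test called 22 probe sets. Leaving out 1 line gave 2 (SW48) to 54 (LS174T) genes, 29 (RKO) to 261 (CACO2) probe sets and 0 to 5 (SKCO1) chromosomes. Of all 27 lists, against 15 called, 1 passed with an estimated correlation, 2 with directional fry, 5 with mixed fry (4 of them among the 15), and 0 with the exact test of scores (lowest adjusted p 0.0714, 3 lists at the smallest p that 5 against 5 lines can give), and 13 to 19 passed without 1 line, of which 12 (without SKCO1) to 15 were among the 15. With the dim filter 6 chromosomes passed and the share of the sum of squares between lines of the same status was 77.5%, against 71.2%. Genes that differ between lines stayed within 1.5 times. Except where fewer genes or lines were tested, the cause was not tested. Values near the array background, as for RNLS in MSI lines (4.18 log2), limit how low a level can be read.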

Other observations

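The test of chromosomes over other splits was chosen only after the result was seen. Among EGFR ligands and MAPK output genes, which did not pass as a list, ETV5, DUSP5 and PHLDA1 differed by 2.22, 2.84 and 1.58, while the receptor genes ERBB3 and ERBB2 differed by -1.62 and -0.74, and none passed over all genes. The mixed fry test of that list, which counts changes in either direction, gave an adjusted p of 0.0262. RPL22L1 differed by 1.91 and its paralog RPL22, a member of the coding-repeat list, by 0.10, at 13.55 ± 0.23 in MSI and 13.45 ± 0.25 in MSS lines. LYZ, counted among the immune markers and also made by secretory cells of the gut, lay at 4.95 ± 1.51 in MSI and 9.37 ± 2.53 in MSS lines, and the other 10 immune markers differed by -0.79 (CD14) to 0.32 (CD8A). HOXD8 lay at 6.71 ± 1.67 in MSI and 4.34 ± 0.07 in MSS lines. These genes were chosen after their values were seen.

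Other splits of the 10 lines into groups of 5 showed how far chance reaches. Of 100 splits, 2 gave at least 9 changed genes, the real one included, and the highest other count was 13, for CACO2, HCT116, LIM2405, RKO and SW48 against the rest, a split that exchanges LS174T and CACO2. For probe sets 1 of 100 splits reached the real count of 103, and the highest other count was 22. For both counts the share of drawn splits that reached the real one was under 0.05, which makes chance less likely without excluding it. For the lists the share was above 0.05: 9 of 100 splits gave at least 15, with a highest other count of 17 and a median of 9 over the other splits. Chance thus stays open for the lists. For chromosomes the real count of 0 was reached by 100 of 100 splits, with a highest other count of 11. Since every split gives at least 0, this says nothing about chance.

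A hypothesis tested here was that runs of neighbouring genes shift together between MSI and MSS lines, as gains or losses shared within a status would make them do. Over 755 windows of 50 neighbouring genes, the largest median shift from the median of all genes was 0.26, on chromosome 9 between EEIG1 and TOR1A, where 41 of 50 genes lay above that median. Of 100 splits of the lines, 90 gave a window at least as far from the median, the real one included, and the highest other value was 0.59. The data gave no sign of such runs beyond what other groupings of the lines show.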
